A study of Mus musculus with 16 samples.

How the data were processed

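The series holds 16 arrays of 2 colours (Agilent 4x44k, mouse), and the samples were grouped from their labels as hFc (4), Dll4-Fc (4), VEGF-A (5) and VEGF Trap (3). Per the labels, retinas of C57Bl6 pups were taken 24 h after an injection into the eye, RNA was purified on columns, and amplified cRNA was labelled with Cy3 for the samples and Cy5 for a common reference pool. No dye was swapped. The dose of VEGF Trap, the meaning of the codes in the titles, the animals behind each sample and the genome build of the probes are not given in the sources used here.

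Per the file headers, the intensity values of both channels came from the scanner software Feature Extraction 9.5.1.1 as mean signals per spot with local background medians. Per the file headers, the log10 LogRatio column holds Cy5 over Cy3 after background subtraction, spatial detrending and dye normalization. The authors deposited a series matrix of natural log ratios. Across probes it equalled the LogRatio column turned to sample over reference and scaled to natural log, at a correlation of at least 0.999 on each array. The deposited flags mark outlier spots and spots well above background, as set by the scanner software per the file headers. No spot was marked as saturated. The median signal per array was 588 to 910 in Cy3 and 515 to 679 in Cy5.

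The columns of the series matrix were not centred, and 25.1 to 27.5% of their cells were empty. Their medians were 0.0184, 0.0155, 0.0186 and 0.00263 for hFc 1 to 4, and 0.00737, 0.0116, 0.0116 and 0.00127 for Dll4-Fc 1 to 4. They were −0.00354, −0.000165, 0.00888, −0.00581 and −0.00401 for VEGF-A 1 to 5, and 0.0146, 0.00603 and 0.0218 for VEGF Trap 1 to 3. How cells came to be empty is not given in the sources used here.

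Intensities were background corrected by normexp with an offset of 50 and normalized within arrays by loess with control spots at weight 0, then turned to log2 of sample over reference. Of 43537 spots on each array, those marked as outliers were left out, and spots of the same probe were averaged. Of 43426 probes, 39788 were kept for being well above background in Cy3 on at least 3 arrays. Probes were named by accession (25775), symbol (7185), older symbol (3283) or the name in the file alone (7183), with names from a RefSeq table. Each gene took its probe with the highest mean intensity, which left 23362 genes, 18470 of them with a symbol of that table. Of these, 542 had no hFc value once outlier spots were left out.

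Genes were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0, data.table version 1.17.8) in a single fit of 4 groups over 16 arrays, with moderated t statistics, 2-sided, and Benjamini-Hochberg adjustment at 0.05 within each of 5 comparisons. The fit had 12 residual and 3.77 prior degrees of freedom, and the median standard error was 0.09 to 0.10. The number of arrays limits the precision of each fold change. Samples, comparisons, gene lists and most alternatives were fixed before the data were examined.

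In total 29 gene lists were tested in 5 comparisons, 145 tests, adjusted over the lists within a comparison. They covered Notch target genes, Notch receptors and ligands, tip cell and sprouting, VEGF-responsive endothelial, pan-endothelial, arterial, venous, endothelial barrier, mural, vasoactive, basement membrane, inflammation, interferon, microglia, neutrophil and erythroid genes. Müller glia, astrocyte, gliosis, rod, cone, bipolar, amacrine and horizontal, ganglion cell, cell cycle, hypoxia, immediate early, lens and pigment epithelium genes made up the rest. Lists overlap, with 14 of 16 tip cell genes and 12 of 21 VEGF-responsive genes in another list. The planned camera test cannot take missing values, so cameraPR ranked the moderated t statistics with a preset correlation of 0.01. The alternatives were a correlation estimated for each list and fry, which tests whether the genes of a list move on balance in the same direction and does not compare them with other genes. Fry and the estimated correlations used only genes with a value on every array.

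Named genes followed a fixed rule. In each comparison with hFc it took the 8 largest rises and 8 largest falls among called genes with a symbol that were well above background on every array of a group, with all treated arrays on the same side of the hFc mean. It added up to 3 called members of each list with the smallest p, and 13 study genes (Vegfa, Kdr, Flt1, Dll4, Notch1, Notch4, Hes1, Hey1, Adm, Agt, Esm1, Angpt2 and Apln). The other 2 comparisons took 5 each way and the study genes. Of called named results, 155 had another probe, 38 had no other probe past the threshold in the same direction, and 0 had a probe past it in the opposite direction. Genes outside the rule are marked as chosen after their values were seen.

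The method was tested on simulated arrays with the means and spreads of the measured genes, 100 of them changed by each of 2 known sizes. At a log2 change of 0.5 it recovered 74% of them for VEGF-A, 71% for Dll4-Fc and 73% for VEGF Trap against hFc, and 67% for VEGF-A against VEGF Trap, and at a change of 1 it recovered 98, 96, 97 and 96%. False calls made up 4.44, 2.91, 4.49 and 5.23% of the calls, and all recovered signs were right. The simulated noise was drawn independently for each gene, with no slide difference and no trend along the rows. The test thus checks the fit under those conditions and does not give the share of false calls on the real arrays.

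Alternatives fixed beforehand were no background subtraction, the LogRatio column, the series matrix values, scale normalization between arrays, and the Cy3 channel alone. Further ones were no filter or a stricter filter on dim probes, slide as a random block, only the groups compared, and every probe tested. In another, the 2 hFc arrays that share the first part of their title code were averaged. The last were eBayes with trend and robust, and each array left out in turn. VEGF-A vs VEGF Trap was also fitted with slide as a fixed block and within each slide. Alternatives chosen after seeing the data were outlier spots kept, the trend along the rows removed, the band of rows on the hFc slide left out, the lens mean as a covariate, and VEGF-A arrays of a single slide. Overlaps were set beside 50 simulated sets and splits of the hFc arrays.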

Results

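The arrays measured mouse retinas 24 h after an injection into the eye of VEGF-A (n = 5), of Dll4-Fc (n = 4), of VEGF Trap (n = 3) or of the Fc part alone, hFc (n = 4). Pups were injected at 8 days with 1 µg of VEGF-A or 4 µg of Dll4-Fc or hFc. The labels give neither age nor dose for VEGF Trap. VEGF-A vs hFc and Dll4-Fc vs VEGF-A thus compare unequal doses. VEGF-A drives the growth of retinal vessels, VEGF Trap binds it, and soluble Dll4 can block signalling of the endothelial ligand Dll4 to Notch receptors. Which Notch signals were blocked in these retinas was not measured. Each array set a sample in Cy3 against a common reference pool in Cy5, and 39788 probes for 23362 genes were kept. The Cy3 signal was well above background for 84.9 to 91.0% of the spots of an array. The first principal component held 35.0% of the variance. The labels do not say which samples came from separate animals, so the p-values measure spread between samples, which may be technical. In the titles hFc 1 and hFc 2 share the first part of their code, as do VEGF-A 4 and VEGF Trap 3. What a shared part means is not stated, and only the hFc pair was averaged in an alternative. With hFc 1 and hFc 2 averaged, 2210 genes were called for VEGF-A, 1000 for Dll4-Fc and 1206 for VEGF Trap against hFc. Where a gene had a single array measured in a group, its spread was assumed to be that of the other groups.

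All hFc arrays lay on 1 slide and all Dll4-Fc arrays on another, while VEGF-A and VEGF Trap shared 2 slides. No comparison with hFc or with Dll4-Fc can therefore by itself tell slide from treatment. The number that opens each title code also went with the slide, so what it stands for cannot be told from slide either. Arrays of the same group had a median correlation of 0.56 when they shared a slide (17 pairs) and 0.54 when they did not (8 pairs), across genes, which are not independent replicates. Arrays of different groups had −0.08 on the same slide (7 pairs) and 0.04 on different slides (88 pairs). Single pairs of VEGF-A arrays had 0.593 to 0.857 on the same slide and 0.377 to 0.557 on different slides. The VEGF Trap pair on the same slide had 0.664, and those on different slides 0.717 and 0.639. The lowest correlations were −0.365 between Dll4-Fc 3 and VEGF-A 2, then −0.333, −0.323 and −0.313. The direction of all arrays was kept, because the labels state the dyes for each array and the conditions could oppose each other. The hFc arrays carried 2350 to 2599 spots marked as outliers against 12 to 213 on the others, most of them in a band of rows.

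**Figure D1:**
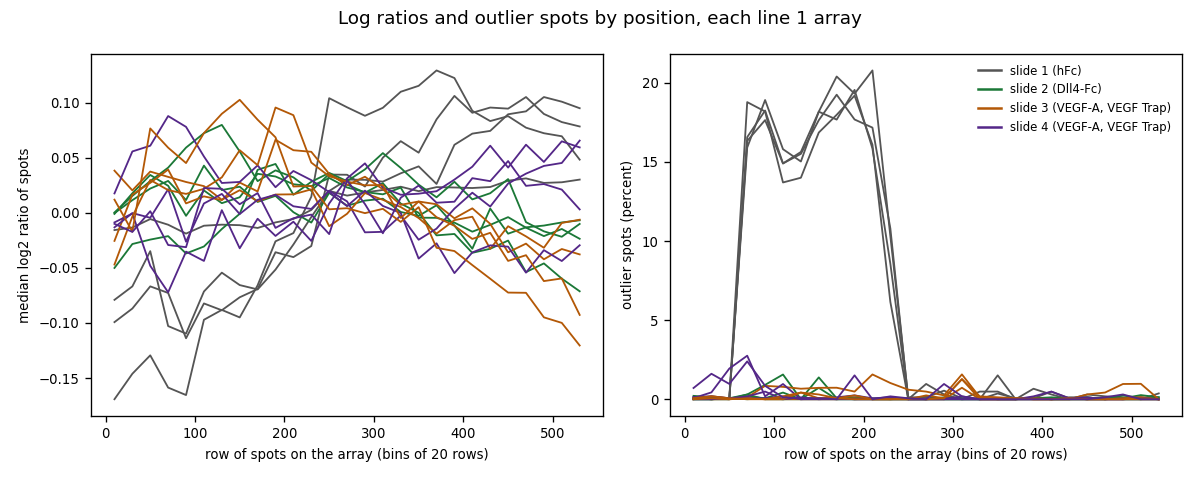
Median log2 ratio (left) and percentage of spots marked as outliers (right) along the rows of each array, 1 line per array, coloured by slide. On the hFc arrays the share reached 20.8% in a band of rows, against at most 2.75% on the other arrays.

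VEGF-A vs hFc asked what extra VEGF-A changed in the growing retina. Genes of sprouting endothelium were among the largest rises, as were the mural genes Acta2 and Tagln. Esm1, a secreted proteoglycan of endothelial tip cells, rose 101-fold (log2 6.66, standard error 0.27, 5 VEGF-A and 4 hFc arrays, adjusted p = 5.14e-11), with 4.08, 6.44 and 4.09 on its other probes. The potassium channel subunit Kcne3 rose 20.6-fold (4.37, 0.15) and the urokinase receptor Plaur 18.6-fold (4.22, 0.12). Dll4, the Notch ligand of tip cells, rose 3.69-fold (1.88, 0.07, adjusted p = 8.41e-12), with 0.78 and 1.19 on its other probes. Apln rose 6.62-fold (2.73, 0.11), with 1.47 to 2.80 on its other probes, and Angpt2 6.50-fold with a single hFc array measured (2.70, 0.15). Notch4 rose 2.51-fold with 4 VEGF-A arrays measured (1.33, 0.08), with 0.59 on another Notch4 probe. Ch25h, a cholesterol hydroxylase, rose 39.8-fold (5.32, 0.33), the endothelin Edn2 13.1-fold (3.71, 0.22), and the calcitonin gene Calca 12.2-fold (3.61, 0.19), though another Calca probe gave 0.31. By limma's moderated t statistics, 2787 of 22820 genes passed an adjusted p of 0.05, of which 1597 rose and 1190 fell. Falls outnumbered rises with the band of rows left out (1241 and 1152) and with the VEGF-A arrays of slide 3 only (1800 and 1666). With the band left out the median log2 change of all genes was also lower, at −0.058 against −0.025. At least 2-fold rises numbered 365 and falls 41. The count was 1857 with the Cy3 channel alone.

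In VEGF-A vs hFc the largest fall among the named genes with an hFc value was in Slco1c1, a thyroid hormone transporter of barrier endothelium, which fell 8.42-fold (log2 −3.07, standard error 0.15, adjusted p = 5.26e-10). Kcnj8, a pericyte channel subunit, fell 4.53-fold (−2.18, 0.15), and Ndufa4l2 fell 3.60-fold (−1.85, 0.10). Apod fell 4.14-fold (−2.05, 0.19) and Aqp4, the water channel of glial endfeet, 3.44-fold (−1.78, 0.23). The noncoding RNA H19 fell 3.34-fold (−1.74, 0.21), Depp1 3.01-fold (−1.59, 0.16), and Angpt4 3.09-fold (−1.63, 0.11), with −0.07 and 0.14 on the other Angpt4 probes. Vegfa itself fell 2.16-fold (−1.11, 0.14, adjusted p = 2.99e-05), and by −0.72 with the VEGF-A arrays of slide 3 only. Mfsd2a, a lipid transporter of barrier endothelium, fell 1.99-fold (−0.99, 0.14) while Plvap, a protein of leaky endothelium, rose 3.53-fold (1.82, 0.12).

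Among Notch and receptor genes in VEGF-A vs hFc, Hes1 rose by 0.57 (standard error 0.14, adjusted p = 0.0124). The call for Hes1 was lost in several settings, among them the LogRatio column at 0.44, the VEGF-A arrays of slide 4 only at 0.46, and the fit without hFc 2 at 0.47. Kdr gave 0.29 (adjusted p = 0.170) and Hey1 0.11 (0.347). Notch1 gave 0.38 (0.139), and passed without VEGF-A 3 at 0.48 and with the VEGF-A arrays of slide 3 only at 0.60, against 0.23 with those of slide 4 only. Adm gave −0.53 (0.138), and passed without VEGF-A 3 at −0.77 and with the VEGF-A arrays of slide 3 only at −0.79. Flt1 gave 0.66 with a single hFc array measured (0.0687), while another Flt1 probe gave 2.24 and its remaining probes 0.11 and 0.04. Agt had no hFc value.

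Endothelial gene lists rose in VEGF-A vs hFc. Of 15 measured genes of tip cells and sprouting, 11 rose and 1 fell, and 12 and 2 adjusted over the list alone (median log2 2.00, list test adjusted p = 1.33e-19). The 1 that fell was Cxcr4 (−0.64), chosen after its value was seen. VEGF-responsive endothelial genes rose in 14 of 21 and fell in 1, and 17 and 2 adjusted over the list alone (1.23, adjusted p = 6.98e-22), with Adamts1 5.29-fold up. Pan-endothelial genes rose in 11 of 19 and fell in 2, and 14 and 3 adjusted over the list alone (0.79, adjusted p = 1.03e-11), with Mmrn2 3.26-fold and Icam2 3.07-fold up. Basement membrane and matrix genes rose in 10 of 14 and fell in 0, and 11 and 0 adjusted over the list alone (1.04, and 0.62 with the band of rows left out, adjusted p = 2.68e-09), with Lama4 4.22-fold up, though 1 of its other probes gave −0.08. Notch receptors and ligands rose in 3 of 7 and fell in 0, with the same counts adjusted over the list alone (0.38, adjusted p = 0.000667), at 0.23 with the VEGF-A arrays of slide 4 only. Arterial genes rose in 3 of 11 and fell in 1, also adjusted over the list alone (0.11, adjusted p = 0.0341), and adjusted p = 0.0789 with an estimated correlation. The arterial call was lost without hFc 3 at 0.14, without VEGF-A 4 at 0.09 and with the VEGF-A arrays of slide 3 only at 0.06, and the median was 0.07 without hFc 2 and 0.03 with the row trend removed. The list test asked whether the genes of a list ranked higher or lower than all others.

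Mural cell genes split in VEGF-A vs hFc, with 7 up and 4 down of 16, and the same counts adjusted over the list alone. Smooth muscle actin Acta2 rose 16.8-fold (log2 4.07, standard error 0.20), but by 1.24 in the Cy3 channel alone and by 1.29, 0.74 and 3.36 on its other probes. Transgelin, Tagln, rose by 4.00 (0.13) and Mcam 5.63-fold (2.49, 0.06). Chosen after their values were seen, Cnn1 rose by 2.33, Des by 1.69, Cspg4 by 1.48 and Myl9 by 1.43. The falls were Kcnj8 and, chosen in the same way, Higd1b (−1.31), Anpep (−1.14) and Abcc9 (−0.83). The list median was 0.37, and 0.25 with the band of rows left out (adjusted p = 0.000782, and adjusted p = 0.0789 with an estimated correlation).

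Proliferation, glial stress and early response genes rose in VEGF-A vs hFc. All 20 measured cell cycle genes rose, also adjusted over the list alone (median log2 1.34, list test adjusted p = 5.85e-34), with Ccnb1 4.91-fold and Birc5 4.65-fold up. Gliosis and retinal stress genes rose in 12 of 17 and fell in 0, with the same counts adjusted over the list alone (0.89, adjusted p = 5.75e-17). The intermediate filaments of reactive glia were among them, with Nes 4.85-fold (2.28, standard error 0.08) and Vim 3.58-fold (1.84, 0.12). Immediate early genes rose in 9 of 13 and fell in 0, and 10 and 0 adjusted over the list alone (0.89, adjusted p = 2.44e-12), with Egr2 7.08-fold and Egr1 4.74-fold up. The monocyte chemokine Ccl2 rose by 3.33 (0.36, adjusted p = 5.56e-06). Inflammation and adhesion genes rose in 5 of 15 and fell in 1, and 6 and 2 adjusted over the list alone (0.10, adjusted p = 0.0187), and adjusted p = 0.329 with an estimated correlation. That call was lost without hFc 3 at 0.05 and with the VEGF-A arrays of slide 3 only at 0.02, and with the band of rows left out the median was −0.03.

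Hypoxia and glycolysis genes, which low oxygen raises, went down in VEGF-A vs hFc in 6 of 21 and up in 0, and 13 and 0 adjusted over the list alone (median log2 −0.30, list test adjusted p = 7.63e-07, and adjusted p = 0.0789 with an estimated correlation). Bnip3 fell 2.12-fold. Erythroid genes rose in 4 of 8 and fell in 0, and 5 and 0 adjusted over the list alone (0.34, adjusted p = 0.00476, and adjusted p = 0.208 with an estimated correlation), a call lost with the VEGF-A arrays of slide 3 only at 0.22. Amacrine and horizontal cell genes fell in 2 of 14 and rose in 0, and 3 and 0 adjusted over the list alone (−0.17, adjusted p = 0.0341), a call lost without VEGF-A 1 at −0.13, without VEGF-A 2 at −0.14, with the VEGF-A arrays of slide 4 only at −0.11 and with the band of rows left out at −0.25. Retinal ganglion cell genes fell in 1 of 12 and rose in 0, with the same counts adjusted over the list alone (−0.40, adjusted p = 0.0341, and adjusted p = 0.531 with an estimated correlation). That call was lost with the band of rows left out at −0.35, without hFc 3 at −0.36, without VEGF-A 1 at −0.23 and without VEGF-A 2 at −0.26. The ganglion cell median was −0.85 with the VEGF-A arrays of slide 3 only and −0.03 with those of slide 4 only.

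No call was made in VEGF-A vs hFc for Notch target genes, with 4 up and 2 down of 12 (median log2 0.11, adjusted p = 0.112), though they passed without VEGF-A 3 at 0.12. Müller glia genes had 4 up and 2 down of 12 (0.112), venous genes 2 up of 4 (0.0681), passing without hFc 1 at 0.27 and without VEGF-A 5 at 0.28, and astrocyte genes 2 up of 7 (0.190). Of the 6 venous genes, Slc38a5 and Aplnr had no hFc value and are not in these counts. With outlier spots kept they gave −3.41 and −1.52, so the venous values hold only for the genes measured. Barrier genes had 3 up and 5 down of 12 (0.858). Vasoactive genes had 5 up and 3 down of 21 with a median of −0.01, a mean of 0.14 and a list test pointing up (0.376). Microglia and macrophage genes had 3 down of 14 (0.0962), and passed with the VEGF-A arrays of slide 4 only at −0.19, as did bipolar cell genes at −0.19. No member passed among interferon genes (0.599) or neutrophil genes, with a median of −0.04 and a test pointing up (0.899). With all arrays, rod (0.858), cone (0.417), bipolar (0.417), lens (0.599) and retinal pigment epithelium genes (0.810) passed in neither direction.

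**Figure D2:**
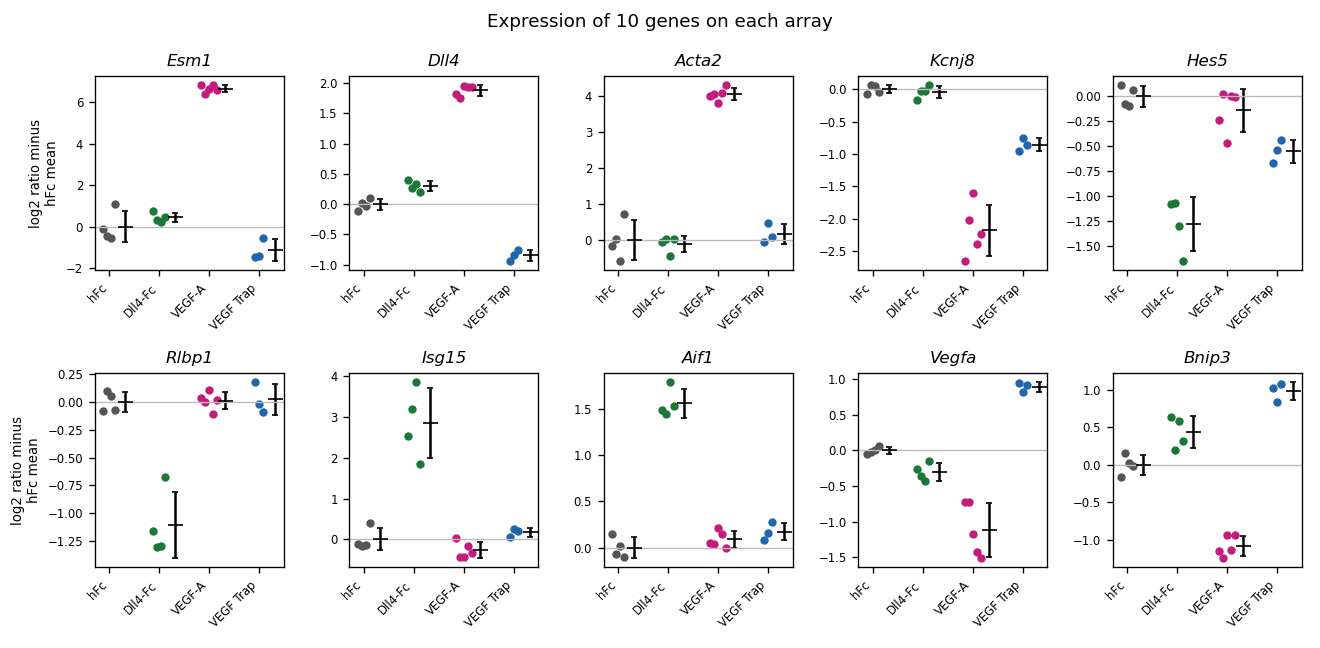
Log2 ratio of 10 genes on each array minus the hFc mean, by group, with 1 point per array. Esm1 rose by 6.66 after VEGF-A and Isg15 by 2.85 after Dll4-Fc, while Bnip3 rose by 0.99 after VEGF Trap.

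Dll4-Fc vs hFc asked what injected Dll4-Fc changed, and innate immune genes rose most. Complement factor Cfb rose 17.7-fold (log2 4.15, standard error 0.27, 4 arrays in each group, adjusted p = 8.67e-08). The interferon-induced genes Usp18 (log2 3.58, 0.45), Ifi27l2a (11.5-fold, 3.53, 0.26) and Bst2 (9.86-fold, adjusted p = 1.01e-06) rose as well. So did the chemokine Ccl5 (10.1-fold), Isg15 (7.22-fold, adjusted p = 9.44e-06) and Oasl2 (5.47-fold). Spp1 rose 11.9-fold with 2 hFc arrays measured. Pmch rose 14.3-fold, with 0.38 on another Pmch probe, and Ifi204 by 3.33, with 0.01 on another Ifi204 probe. By limma's moderated t statistics, 1202 of 22820 genes passed an adjusted p of 0.05, of which 760 rose and 442 fell, with 233 rises and 50 falls of at least 2-fold. With the band of rows left out 445 rose and 422 fell, and the median log2 change of all genes moved from −0.015 to −0.054. Each group filled a slide of its own, so slide and group cannot be told apart.

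The largest falls in Dll4-Fc vs hFc included genes of Müller glia, the radial glia of the retina. Abca8a fell 11.6-fold (log2 −3.53, standard error 0.14, adjusted p = 4.97e-10), the caveolar protein Cav1 5.55-fold (−2.47, 0.11) and Gdpd2 4.28-fold (−2.10, 0.14). Frzb fell 3.15-fold (−1.66, 0.10), Krt19 3.33-fold (−1.74, 0.19) and Metrn 2.88-fold (−1.52, 0.16). Gm2115 fell 3.47-fold, with 0.10 on another Gm2115 probe, and Egfl6 2.97-fold, by −2.83 with the LogRatio column. Of 12 measured Müller glia genes 8 fell and 0 rose, and 10 and 0 adjusted over the list alone (median −0.64, list test adjusted p = 3.39e-11). The retinoid binding protein Rlbp1 fell 2.15-fold (−1.11, 0.11) and Car2 1.53-fold (−0.61, 0.10). Slc1a3 fell 1.89-fold (−0.92, 0.14), with −0.81, −0.86, −0.20 and −0.00 on its other probes.

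Notch target genes went down in Dll4-Fc vs hFc, with 0 up and 5 down of 12, and 1 and 9 adjusted over the list alone (median log2 −0.41, list test adjusted p = 2.07e-07). Hes5, a Notch effector of neural progenitors and glia, fell 2.43-fold (−1.28, standard error 0.13, adjusted p = 7.95e-06). Hey2 fell 1.83-fold with 3 hFc arrays measured (−0.87, 0.11). Hes1 fell by 0.62 (adjusted p = 0.0181), a call lost without hFc 4 at −0.49, without Dll4-Fc 3 at −0.54 and without Dll4-Fc 4 at −0.56. Hey1 fell by 0.37, but gave −0.28 with the LogRatio column and −0.23 with the Cy3 channel alone, which ended the call. The ligand Dll1 rose 2.23-fold (1.16, 0.20). Dll4 rose by 0.30 (adjusted p = 0.0129), with 0.15 and 0.13 on its other probes, a call lost without Dll4-Fc 1 at 0.27. Notch1 gave 0.18 (0.617) and Notch4 0.20 (0.225). Notch receptors and ligands had 2 up of 7 (adjusted p = 0.0777), and passed without Dll4-Fc 3 at a median of 0.24.

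Interferon response genes rose in 14 of 17 in Dll4-Fc vs hFc and fell in 0, and 17 and 0 adjusted over the list alone (median log2 1.94, list test adjusted p = 9.38e-25). The mean of these genes was 0.164 to 1.81 on the Dll4-Fc arrays and −1.11 to −0.717 on the hFc arrays. Microglia and macrophage genes rose in 13 of 14 and fell in 1, with the same counts adjusted over the list alone (0.72, adjusted p = 1.55e-18). The microglial actin-binding protein Aif1 rose 2.95-fold (1.56, standard error 0.08, adjusted p = 8.68e-09) and Fcer1g 2.87-fold with a single hFc array measured. Itgam rose 1.91-fold, with 0.16 on another Itgam probe. The 1 that fell was P2ry12 (−0.38), chosen after its value was seen. Inflammation and adhesion genes rose in 6 of 15 and fell in 1, and 8 and 1 adjusted over the list alone (0.67, adjusted p = 7.24e-07). Their mean was −0.198 to 0.758 on the Dll4-Fc arrays and −0.549 to −0.302 on the hFc arrays. Icam1 rose 1.59-fold, with 0.35 on another Icam1 probe, which did not pass, while Vcam1 fell 2.53-fold, with 0.09, −0.72, −1.20 and −1.42 on its other probes. Gliosis and retinal stress genes rose in 7 of 17 and fell in 0, and 8 and 0 adjusted over the list alone (0.38, adjusted p = 4.48e-08), with complement C4b 2.97-fold and Gfap 1.99-fold up. Neither of the other Gfap probes passed (0.79 and 0.44).

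Endothelial genes moved little in Dll4-Fc vs hFc. Pan-endothelial genes rose in 4 of 19 and fell in 1, and 5 and 2 adjusted over the list alone (median log2 0.19, and 0.11 with the band of rows left out, list test adjusted p = 0.000426, and adjusted p = 0.0656 with an estimated correlation). Tip cell and sprouting genes rose in 4 of 15 and fell in 1, and 8 and 2 adjusted over the list alone (0.30, adjusted p = 0.00494). Egfl7 rose 1.46-fold and Mmrn2 1.44-fold, with 0.30 on another Mmrn2 probe. Kcne3 rose 1.84-fold, and gave 1.24 without a call after scale normalization. Kdr fell by 0.51 (adjusted p = 0.0406), a call lost in 14 of 24 settings. Among them were the fits without hFc 1 (−0.54), hFc 2 (−0.46), hFc 3 (−0.51), hFc 4 (−0.54), Dll4-Fc 1 (−0.45), Dll4-Fc 2 (−0.41) and Dll4-Fc 3 (−0.50), and neither of the other Kdr probes passed (−0.45 and −0.45). Esm1 gave 0.45 (0.452) and passed without hFc 4 at 0.81, and Flt1 gave −0.67 (0.125) and passed without Dll4-Fc 4 at −0.81, with −0.05 to −0.01 on its other probes. Vegfa gave −0.30 (0.316), Adm 0.67 (0.137), Apln −0.20 (0.382) and Angpt2 0.02 with a single hFc array measured (0.972).

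Cell cycle genes rose in Dll4-Fc vs hFc in 3 of 20 and fell in 0, and 12 and 0 adjusted over the list alone (median log2 0.31, list test adjusted p = 1.12e-08, and adjusted p = 0.0656 with an estimated correlation), with Birc5 1.78-fold and Ccnb2 1.55-fold up. Hypoxia and glycolysis genes rose in 2 of 21 and fell in 0, and 4 and 0 adjusted over the list alone (0.16, and 0.09 with the row trend removed, adjusted p = 0.00461, and adjusted p = 0.449 with an estimated correlation). Immediate early genes rose in 1 of 13 and fell in 0, with the same counts adjusted over the list alone (0.19, adjusted p = 0.00633, and adjusted p = 0.132 with an estimated correlation). Basement membrane genes rose in 3 of 14 and fell in 0, also adjusted over the list alone (0.19, adjusted p = 0.0490, and adjusted p = 0.485 with an estimated correlation), a call lost in 10 of 21 settings. Among them were the fits without hFc 1 (0.19), hFc 2 (0.16), hFc 3 (0.06), Dll4-Fc 1 (0.18) and Dll4-Fc 4 (0.18), and without hFc 4 the median was 0.37. VEGF-responsive endothelial genes had 4 up and 2 down of 21, with a median of 0.02 and a mean of −0.03 (0.857). Lens genes had a median of 1.05 without a call (0.181), and passed without hFc 4 at 2.09 and without Dll4-Fc 4 at 1.85. Mural (0.284), vasoactive (0.640), arterial (0.640), venous (0.337), barrier (0.143), erythroid (0.559) and ganglion cell genes (0.948) passed in neither direction.

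VEGF Trap vs hFc asked what binding VEGF changed, and genes of the response to low oxygen rose. Bnip3 rose 1.98-fold (log2 0.99, standard error 0.11, 3 VEGF Trap and 4 hFc arrays, adjusted p = 0.000168), and the glycolytic genes Pdk1 1.89-fold (0.92, 0.12) and Pgk1 1.58-fold (0.66, 0.10). Vegfa, which low oxygen induces, rose 1.86-fold (0.90, 0.16, adjusted p = 0.00457). Of 21 hypoxia and glycolysis genes 14 rose and 0 fell, and 18 and 0 adjusted over the list alone (median 0.62, list test adjusted p = 3.77e-17). The largest rises included Gipr (3.63-fold, with 1.01 and 0.57 on its other probes), Muc2 (3.53-fold, with 0.07 on another Muc2 probe), Serpine3 (3.27-fold) and Lcat (2.63-fold, 1.39, 0.10). By limma's moderated t statistics, 1785 of 22820 genes passed an adjusted p of 0.05, of which 607 rose and 1178 fell, with 26 rises and 21 falls of at least 2-fold. There were 324 rises and 1361 falls with the band of rows left out, 313 and 939 with the row trend removed, and 1092 and 1229 with only the groups compared. With the band left out the median log2 change of all genes was −0.069, against −0.025 with all rows. The count fell to 350 without VEGF Trap 1, 904 without hFc 2 and 962 without hFc 3. It was 850 with the LogRatio column, 1107 with the series matrix and 449 with the Cy3 channel alone.

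Endothelial genes went down in VEGF Trap vs hFc, with 0 up and 13 down of 19 pan-endothelial genes, and 0 and 14 adjusted over the list alone (median log2 −0.55, list test adjusted p = 2.73e-13). The angiopoietin receptor partner Tie1 fell 1.74-fold (−0.80, standard error 0.09), Icam2 1.85-fold (−0.88, 0.10) and the tight junction protein Cldn5 1.54-fold (−0.62, 0.08). Dll4 fell 1.80-fold (−0.85, 0.07, adjusted p = 2.51e-05), with −0.09 and −0.57 on its other probes, and Notch4 1.67-fold (−0.74, 0.09), with −0.17 on another Notch4 probe. Prnd fell 2.50-fold (−1.32, 0.13) and Mfsd2a 2.38-fold (−1.25, 0.16). Kcne3 fell 3.68-fold (−1.88, 0.17), and gave −1.15 without a call after scale normalization. Esm1 fell by 1.15 (adjusted p = 0.0353), a call lost without hFc 1 at −1.18, without VEGF Trap 1 at −0.98 and without VEGF Trap 2 at −1.01, and −0.20 after scale normalization. None of the other Esm1 probes passed (−0.47, −0.95 and −0.33). Apln rose 1.84-fold (0.88, 0.12), with 0.97, 0.94, 0.23 and 0.31 on its other probes, and gave 1.19 without a call after scale normalization.

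Tip cell and sprouting genes fell in 7 of 15 in VEGF Trap vs hFc and rose in 1, and 7 and 2 adjusted over the list alone (median log2 −0.18, list test adjusted p = 0.00728), a call lost after scale normalization at −0.15. The tip cell median was −0.32 without hFc 1 and −0.32 without hFc 2, and −0.38 with the band of rows left out. Arterial genes fell in 3 of 11 and rose in 0, and 5 and 0 adjusted over the list alone (−0.16, adjusted p = 0.00581), with the gap junction gene Gja4 1.42-fold down. Mural genes fell in 7 of 16 and rose in 0, and 8 and 0 adjusted over the list alone (−0.35, adjusted p = 0.000875, and adjusted p = 0.140 with an estimated correlation). Higd1b fell 2.17-fold and Des 1.85-fold. Cell cycle genes fell in 9 of 20 and rose in 0, and 14 and 0 adjusted over the list alone (−0.36, adjusted p = 8.53e-07, and adjusted p = 0.193 with an estimated correlation). Erythroid genes fell in 2 of 8 and rose in 0, and 4 and 0 adjusted over the list alone (−0.38, adjusted p = 0.0221, and adjusted p = 0.432 with an estimated correlation), a call lost without VEGF Trap 3 at −0.34, and −0.61 with the band of rows left out. Apod fell 2.39-fold and Ctsw 2.55-fold.

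In the list lens, VEGF Trap vs hFc gave 0 rises and 0 falls of 14 genes of lens tissue, with a median log2 of 1.95 (list test adjusted p = 0.00728, and adjusted p = 0.596 with an estimated correlation). The lens value was 0.78 without VEGF Trap 2, 1.59 without hFc 3, 3.17 without hFc 4 and 3.53 without VEGF Trap 1, and the call was lost in the first 2 of these. Adm gave 0.68 (adjusted p = 0.109), Kdr −0.18 (0.459), Notch1 −0.26 (0.363), Hes1 −0.08 (0.775) and Hey1 0.04 (0.793). With a single hFc array measured, Flt1 gave −0.05 (0.901) and Angpt2 −0.18 (0.487). Notch target (0.148), VEGF-responsive endothelial (0.253), basement membrane (0.254), microglia (0.197) and Müller glia genes (0.729) passed in neither direction. Interferon genes did not pass (0.137) but did without hFc 4 at 0.31.

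**Figure D3:**
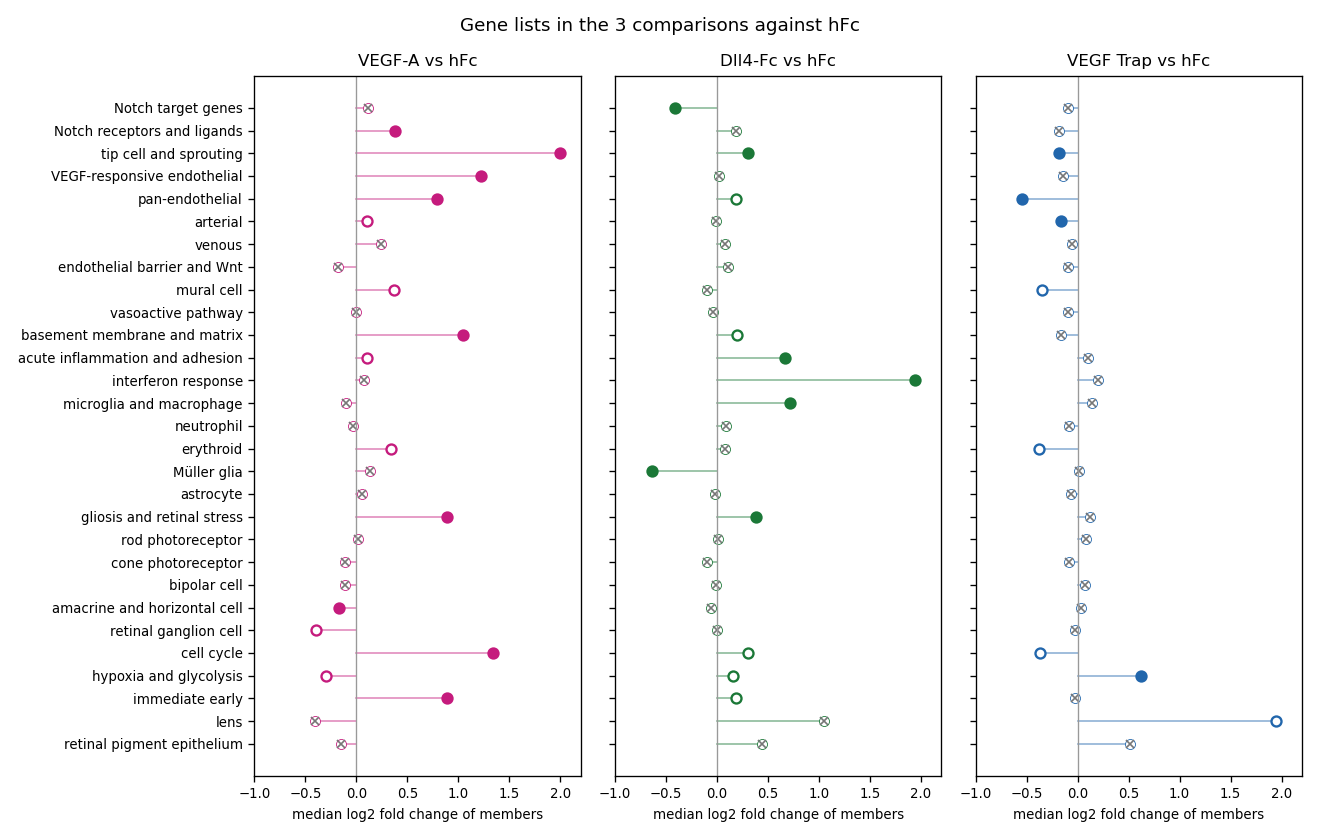
Median log2 fold change of 29 gene lists in each comparison with hFc. Filled points passed with an estimated correlation, open points with the preset correlation only, and grey crosses in neither, with tip cell genes at 2.00 after VEGF-A and interferon genes at 1.94 after Dll4-Fc.

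VEGF-A vs VEGF Trap asked which genes differed between adding and binding VEGF, on slides that held both groups. Slide 4 held a single VEGF Trap array, whose spread was assumed to be that of the others, so values within slide 4 rest on that array. Esm1 was 224-fold higher after VEGF-A (log2 7.81, 5 VEGF-A and 3 VEGF Trap arrays, adjusted p = 1.57e-11), at 7.71 with slide as a block, 8.07 within slide 3 and 7.23 within slide 4. Its other probes gave 4.55, 7.39 and 4.42. Kcne3 was 75.9-fold higher (6.25, then 6.17, 6.34 and 5.95) and Plaur 35.9-fold higher (5.17, then 5.14, 5.26 and 4.99). Ch25h was higher by 4.08 (4.01, 3.71 and 4.41). Dll4 was 6.64-fold higher (2.73, then 2.69, 2.68 and 2.71, adjusted p = 3.89e-13) and Notch4 higher by 2.07 (2.06, 1.91 and 2.27), with 0.87 and 1.77 on other Dll4 probes and 2.08 and 0.77 on other Notch4 probes. Angpt2 was higher by 2.89 (2.81, 2.80 and 2.83) and Apln, which rose against hFc after both, by 1.85 (1.80, 1.89 and 1.67), with 1.16 to 1.83 on its other probes. By limma's moderated t statistics, 4789 of 23362 genes passed an adjusted p of 0.05, of which 2786 were higher after VEGF-A and 2003 lower. With slide as a block 3929 passed, 3579 of them shared, and 3311 within slide 3 and 1650 within slide 4.

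Lower in VEGF-A vs VEGF Trap were the amino acid transporter Slc38a5 of barrier endothelium, 5.96-fold (log2 −2.57, and −2.61 with slide as a block, −2.88 within slide 3, −2.25 within slide 4), and Slco1c1 (−2.55, then −2.45, −2.51 and −2.36). Ndufa4l2 was lower by −2.93 (−2.99, −2.91 and −3.10), Muc2 by −2.96 (−2.93, −2.69 and −3.26, with −0.12 on another Muc2 probe, which did not pass) and Serpine3 by −2.54 (−2.47, −1.92 and −3.19). Vegfa was lower by −2.01 (−1.90, −1.60 and −2.30). Adm was lower by −1.21 (−1.33, −1.31 and −1.36), and did not pass within slide 4. Flt1 was higher by 0.72 (0.72, 0.55 and 0.96), and its other probes gave 2.59, 0.11 and 0.18. Hes1 was higher by 0.65 (0.71, 0.73 and 0.69), and did not pass within slide 4. Kdr was higher by 0.47 (0.50, 0.56 and 0.41), a call lost within slide 4, without VEGF-A 1 at 0.44, without VEGF Trap 2 at 0.41 and without VEGF Trap 3 at 0.47. Notch1 was higher by 0.64 (0.72, 0.81 and 0.59), a call lost within slide 4, without VEGF Trap 1 at 0.64 and without VEGF Trap 3 at 0.59, and neither of its other probes passed (0.31 and 0.58). Hey1 gave 0.08 and Agt −0.10 without a call.

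Lists in VEGF-A vs VEGF Trap moved as follows, each with its median log2 and then the values with slide as a block, within slide 3 and within slide 4. All 20 cell cycle genes were higher, also adjusted over the list alone (1.76, 1.77, 1.75 and 1.62, list test adjusted p = 5.68e-30). With the same counts adjusted over the list alone, pan-endothelial genes were higher in 18 of 20 (1.36, 1.36, 1.25 and 1.51, adjusted p = 1.24e-20), tip cell genes in 13 of 16 and lower in 1 (1.88, 1.89, 1.88 and 1.96, adjusted p = 1.04e-18), and VEGF-responsive genes in 16 of 21 (1.25, 1.26, 1.17 and 1.35, adjusted p = 7.89e-18). Hypoxia and glycolysis genes were lower in 18 of 21, and 19 adjusted over the list alone (−0.99, −0.95, −0.89 and −1.05, adjusted p = 6.3e-19). Immediate early genes were higher in 12 of 14 (0.76, 0.77, 0.80 and 0.77, adjusted p = 2.64e-10) and gliosis genes in 11 of 18 (0.80, 0.76, 0.68 and 0.88, adjusted p = 2.65e-08), also adjusted over the list alone. Mural genes were higher in 8 of 16 and lower in 2, also adjusted over the list alone (0.33, 0.35, 0.33 and 0.57, adjusted p = 2.72e-05). Erythroid genes were higher in 6 of 8, and 7 adjusted over the list alone (0.69, 0.65, 0.69 and 0.66, adjusted p = 3.04e-05). Notch target genes were higher in 6 of 12 and lower in 2, also adjusted over the list alone (0.30, 0.32, 0.41 and 0.23, adjusted p = 0.00741).

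Other vessel lists were higher in VEGF-A vs VEGF Trap. Basement membrane genes were higher in 9 of 14, and 10 with 1 lower adjusted over the list alone (median log2 1.02, with slide as a block 1.04, within slide 3 1.11 and within slide 4 1.23, list test adjusted p = 2.57e-07), at 0.47 with the band of rows left out. Arterial genes were higher in 6 of 11, and 6 with 1 lower adjusted over the list alone (0.25, then 0.24, 0.24 and 0.27, adjusted p = 0.000822). Notch receptors and ligands were higher in 3 of 9 and lower in 1, and 4 and 2 adjusted over the list alone (0.19, then 0.23, 0.14 and 0.27, adjusted p = 0.0339, and adjusted p = 0.194 with an estimated correlation). That call was lost within slide 4, without VEGF-A 1 at 0.15 and without VEGF-A 2 at 0.16.

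The slides differed for some lists in VEGF-A vs VEGF Trap. Astrocyte genes did not pass with all arrays (median log2 0.10, list test adjusted p = 0.0608). They did with slide as a block at 0.15 and within slide 3 at 0.18. Rod genes gave −0.14 without a call with all arrays, but passed within slide 3 at −0.27. Bipolar cell genes gave −0.14 with all arrays, without a call, and −0.37 within slide 4. Retinal ganglion cell genes were lower in 2 of 12, and 1 adjusted over the list alone (median log2 −0.34, −0.51 with slide as a block, list test adjusted p = 0.0270, and adjusted p = 0.517 with an estimated correlation), with −0.86 within slide 3 and 0.03 within slide 4. That call was lost without VEGF-A 1 at −0.21, without VEGF-A 2 at −0.23 and without VEGF Trap 1 at −0.33. Amacrine and horizontal cell genes were lower in 5 of 15, also adjusted over the list alone (−0.21, −0.31 with slide as a block, adjusted p = 0.00866), with −0.35 and −0.11, and lost the call within slide 4. Microglia genes were lower in 4 of 15, and 5 adjusted over the list alone (−0.22, −0.24 with slide as a block, adjusted p = 0.00741, and adjusted p = 0.222 with an estimated correlation), with −0.08 and −0.28, and lost the call within slide 3. Lens genes were higher or lower in 0 of 14 (−2.52, −2.27 with slide as a block, adjusted p = 0.00621, and adjusted p = 0.517 with an estimated correlation), with −0.79 and −4.29, and lost the call within slide 3 and without VEGF Trap 2 at −1.38. Pigment epithelium genes were lower in 1 of 9, and 0 adjusted over the list alone (−0.63, adjusted p = 0.0473, and adjusted p = 0.502 with an estimated correlation), with −0.89 and 0.02. That call was lost with slide as a block at −0.55 (adjusted p = 0.0900), within slide 4, without VEGF-A 1 at −0.67, without VEGF-A 2 at −0.61, without VEGF-A 5 at −0.55 and without VEGF Trap 2 at −0.20.

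Dll4-Fc vs VEGF-A asked where the effects of the 2 treatments differed. Pmch was 31.7-fold higher after Dll4-Fc (log2 4.99, and 0.66 on another Pmch probe), Cfb 19.7-fold, and the proneural transcription factor Neurog2 17.2-fold (4.10, 4 Dll4-Fc and 5 VEGF-A arrays, adjusted p = 1.19e-09). Ifi27l2a was higher by 3.91. Esm1 was 74.2-fold lower after Dll4-Fc (−6.21, adjusted p = 1.08e-10), with −4.28, −6.05 and −4.07 on its other probes. Calca (−4.74, and −0.37 on another probe), Acta2 (−4.18, −1.29 in the Cy3 channel alone, and −3.69, −1.29 and −0.85 on its other probes), Ch25h (−3.88) and Tagln (−3.85) were lower as well. Hes1 was lower by −1.18 (adjusted p = 9.35e-06), Hey1 by −0.49 (0.000138) and Agt by −1.18 (1.01e-06). Dll4 was lower by −1.58 (−0.63 and −1.06 on its other probes), Apln by −2.93 (−3.01 to −1.60), Angpt2 by −2.68 and Kdr by −0.81. Notch4 was lower by −1.13 (−1.18 and −0.37 on its other probes, the last not passing) and Flt1 by −1.33 (−2.25, −0.13 and −0.09). Vegfa was higher by 0.82 and Adm was higher (adjusted p = 0.00104), while Notch1 gave −0.20 (0.530). By limma's moderated t statistics, 3227 of 23362 genes passed an adjusted p of 0.05, of which 1473 were higher after Dll4-Fc and 1754 lower.

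In Dll4-Fc vs VEGF-A, interferon genes were higher in 15 of 17, and 16 adjusted over the list alone (median log2 1.94, list test adjusted p = 4.39e-16), and microglia genes higher in 14 of 15 and lower in 1, also adjusted over the list alone (0.91, adjusted p = 2.35e-17). Notch target genes were lower in 8 of 12, and 10 adjusted over the list alone (−0.80, adjusted p = 3.67e-08), and Müller glia genes lower in 9 of 12 and higher in 1, also adjusted over the list alone (−0.95, adjusted p = 2.68e-09). Adjusted over the list alone, 20 cell cycle, 19 VEGF-responsive, 12 tip cell and 13 pan-endothelial genes were lower. Over all genes these were cell cycle genes in 19 of 20 (−0.97, adjusted p = 1.23e-25), VEGF-responsive genes in 18 of 21 (−1.28, adjusted p = 5.75e-27), tip cell genes in 12 of 16 (−1.48, adjusted p = 6.13e-19) and pan-endothelial genes in 13 of 20 against 3 higher (−0.82, adjusted p = 4.8e-10). Hypoxia and glycolysis genes were higher in 15 of 21, and 17 adjusted over the list alone (0.43, adjusted p = 2.81e-11). Mural genes were lower in 9 of 16 and higher in 4, also adjusted over the list alone (−0.42, adjusted p = 8.87e-05). Gliosis genes were lower in 10 of 18 and higher in 3, and 10 and 4 adjusted over the list alone (−0.39, adjusted p = 9.26e-06, and adjusted p = 0.0603 with an estimated correlation), at −1.04 with the band of rows left out.

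Among the remaining lists in Dll4-Fc vs VEGF-A, immediate early genes were lower in 10 of 14 and higher in 1, and 12 and 1 adjusted over the list alone (median log2 −0.60, list test adjusted p = 2.54e-10). Basement membrane genes were lower in 10 of 14 and higher in 2, also adjusted over the list alone (−0.84, and −0.47 with the band of rows left out, adjusted p = 9.23e-07). Arterial genes were lower in 4 of 11 and higher in 1, and 6 and 1 adjusted over the list alone (−0.23, adjusted p = 0.00265). Erythroid genes were lower in 4 of 8, and 5 adjusted over the list alone (−0.31, and −0.70 with the LogRatio column, adjusted p = 0.00848, and adjusted p = 0.228 with an estimated correlation). Amacrine and horizontal cell genes were higher in 2 of 15, and 0 adjusted over the list alone (0.18, adjusted p = 0.0327), at 0.11 without Dll4-Fc 4 and 0.12 without VEGF-A 2, and lost the call without VEGF-A 1 at 0.12. Ganglion cell genes passed with 0 members called, also adjusted over the list alone (0.39, adjusted p = 0.0258, and adjusted p = 0.468 with an estimated correlation), and lost the call without VEGF-A 1 at 0.25 and without VEGF-A 2 at 0.27. Pigment epithelium genes were higher in 1 of 9, also adjusted over the list alone (0.69, adjusted p = 0.0474, and adjusted p = 0.431 with an estimated correlation), and lost the call without Dll4-Fc 4 (0.55) and without VEGF-A 1 (0.73), VEGF-A 2 (0.68), VEGF-A 4 (0.70) or VEGF-A 5 (0.59).

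Overlap of Dll4-Fc and VEGF-A calls asked how many genes changed in both against the same hFc arrays. Of the genes called in both, 205 rose in both, 118 fell in both and 120 went opposite ways, against 53.2, 23.0 and 70.6 for independent lists of the same sizes. Across genes, which are not independent, the fold changes correlated at 0.22, and simulated unchanged groups against shared controls gave 0.56. Their covariance was 0.0192 against a simulated 0.00872. With the hFc arrays split 2 and 2, 77, 76 and 124 genes rose in both against 24.0, 24.9 and 32.5 for independent lists, 36, 35 and 38 fell in both against 5.88, 5.78 and 7.27, and 57, 53 and 63 went opposite ways against 23.7, 24.0 and 31.1, at correlations of 0.14, 0.11 and 0.08. Both parts of each split lay on the hFc slide. A fault of that slide would push both the same way, and neither independent lists nor the simulated groups allow for it.

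VEGF-A and VEGF Trap calls, also against the same hFc arrays, went opposite ways for 323 genes against 114 for independent lists, with 63 up and 120 down in both against 42.5 and 61.4, at a correlation of −0.003 where simulated unchanged groups gave 0.52. With the hFc arrays split, 4, 8 and 16 rose in both against 5.70, 12.2 and 23.3 for independent lists, 21, 25 and 32 fell in both against 6.40, 11.1 and 13.2, and 141, 210 and 190 went opposite ways against 15.8, 29.3 and 42.1. Dll4-Fc and VEGF Trap calls shared 48 rises and 55 falls against 20.2 and 22.8 for independent lists, with 81 genes opposite against 51, at a correlation of 0.21 where simulated unchanged groups gave 0.50. With the hFc arrays split, 6, 10 and 15 rose in both against 2.67, 6.07 and 10.4 for independent lists, 4, 10 and 12 fell in both against 2.58, 4.91 and 7.02, and 31, 55 and 30 went opposite ways against 7.19, 14.3 and 19.6. Here too all split arrays lay on the hFc slide, so its faults stay in the counts of shared direction.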

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

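Tests of the shares of mural and microglial cells, of the trend along the rows, of the hFc slide and of lens tissue were chosen after the results were seen, while the splits of the arrays, both tests of the Cy5 channel and the slide of the Dll4-Fc arrays were set before. For each gene and list printed here, an array was searched for that lay apart from the rest of its group, by a gap of most of the group's range. Of 321 groups 25 held such an array, and chance alone gives about 1 in 20. VEGF Trap, with 3 arrays, was not tested.

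Array hFc 4 lay apart most often. Its log2 ratio was −1.18 for Calca (the other hFc arrays −2.34 to −2.15), −1.80 for Cfb (−3.00 to −2.88), −1.23 for Isg15, 0.13 for Egfl6, −0.60 for Cnn1 and −0.0602 for Myl9. Its list means were 1.21 for lens genes (−2.68 to −2.48), −0.717 for interferon, −0.518 for gliosis, −0.144 for pan-endothelial genes and −0.133 for Notch receptors and ligands. Of the other hFc arrays, hFc 3 stood apart for Krt5 at −2.17, and hFc 1 for Igfbpl1 at −0.62 and bipolar cell genes at −0.00437.

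Array VEGF-A 3 lay apart for Aqp4 at −0.68 (the other VEGF-A arrays −1.47 to −1.28), Adm at 0.18 (−1.09 to −0.91), Vxn at −3.03 and Notch target genes at 0.178. Array VEGF-A 5 lay apart for Ccl2 at 1.48 (0.75 to 0.89), Notch receptors and ligands at −0.066 and inflammation genes at 0.0485. Array Dll4-Fc 4 lay apart for Slc1a3 at −0.45 (−1.34 to −1.21), Vxn at 0.73, barrier genes at 0.178 and rod genes at −0.376.

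Chance in the grouping of the arrays was tested by other splits of the same arrays. For VEGF-A vs hFc, 1 of 100 splits, the real split, gave as many as 2787 genes, and the highest other split gave 1644. For Dll4-Fc vs hFc it was 1 of 35 splits (1202 genes, highest other 2), and for VEGF Trap vs hFc 1 of 35 splits (1785, highest other 1). For VEGF-A vs VEGF Trap it was 1 of 56 splits (4789, highest other 3033), and for Dll4-Fc vs VEGF-A 1 of 100 splits (3227, highest other 2005). In all 5 the real split gave more genes than every other split tried. Outside VEGF-A vs VEGF Trap the real split also parted the slides, so these counts cannot tell treatment from slide. The split with 3033 genes parted the VEGF-A arrays by slide. With slide as a block VEGF-A vs VEGF Trap gave 3929, but no other split was fitted with that block.

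Interferon genes higher after Dll4-Fc may reflect an immune response in the retina, as a hypothesis. The reference channel argued against a difference between slides in Cy5, since the median Cy5 difference of the list was 0.0129 in log2 against a ratio change of 1.94. A fault of the hFc slide was argued against by Dll4-Fc vs VEGF-A, whose arrays lay on other slides (adjusted p = 4.39e-16). A larger share of microglia and macrophages of unchanged expression was argued against as the whole cause. Of 17 interferon genes, 11 rose more than every microglia marker. These values had been seen before, and the test replaced an earlier count of falling microglia markers. It does not bear on incoming cells that express interferon genes more strongly than resident ones. The slide of the Dll4-Fc arrays stays open, because 1 slide held all of them and slide and treatment cannot be told apart.

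Mural cell genes moving apart after VEGF-A may reflect a changed state of pericytes and smooth muscle, as a hypothesis. A changed share of all mural cells alike would move them together, but 7 were called up and 4 down. These are the values that raised the pattern and no separate test. The list mixes genes of smooth muscle and of pericytes, so the counts cannot tell opposite changes in their shares from a changed state. With the trend along the rows of the arrays removed, 7 were up and 4 down. A fault of the hFc slide was argued against for Kcnj8 (−1.37) and Anpep (−0.80) by VEGF-A vs VEGF Trap with slide as a block, where 8 genes were up and 2 down. The other 2 falls did not pass there, with Higd1b at −0.19 (adjusted p = 0.556) and Abcc9 at −0.13 (adjusted p = 0.537), though Higd1b (1.21) and Abcc9 (0.66) were higher in Dll4-Fc vs VEGF-A, whose slides differ.

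Endothelial genes lower after VEGF Trap may reflect loss or silencing of vessels, as a hypothesis. Once the trend along the rows of the arrays was removed, 13 of the 13 called falls passed. The reference channel differed by a median of −0.0407 in log2 Cy5, against a ratio change of −0.55. Lens tissue diluting the retina was argued against by a median of −0.51 with the lens mean as a covariate. Fewer endothelial cells and less RNA per cell were not told apart by any test here.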

How the results depend on the processing

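Settings chosen after the results were seen were outlier spots kept, the row trend removed, the band of rows left out, the lens covariate and VEGF-A arrays of a single slide. Of 145 list tests 71 passed with the preset correlation and 47 with an estimated correlation. For VEGF Trap vs hFc the count of 1785 genes moved to 850 with the LogRatio column, 1107 with the series matrix values and 449 with the Cy3 channel alone. VEGF-A vs hFc moved from 2787 to 1857 with the Cy3 channel alone, and VEGF-A vs VEGF Trap from 4789 to 1650 within slide 4, with its single VEGF Trap array, and 3311 within slide 3. The overlap of Dll4-Fc and VEGF-A calls in the same direction was 323, and 113, 111 and 162 with the controls split, where fewer controls were used. Leaving out 1 array gave 350 to 1540 genes for VEGF Trap vs hFc, 873 to 1157 for Dll4-Fc vs hFc and 1964 to 3069 for VEGF-A vs hFc. The same gave 3212 to 4916 for VEGF-A vs VEGF Trap and 2632 to 3342 for Dll4-Fc vs VEGF-A. The lowest count for VEGF Trap vs hFc came without VEGF Trap 1, and hFc 2 and hFc 3 left 904 and 962. With the band of rows left out, VEGF Trap vs hFc had 324 rises and 1361 falls against 607 and 1178, Dll4-Fc vs hFc 445 and 422 against 760 and 442, and VEGF-A vs hFc 1152 and 1241 against 1597 and 1190. In the same order, the median log2 change of all genes moved from −0.025 to −0.069, from −0.015 to −0.054 and from −0.025 to −0.058. The remaining rows thus carry a downward shift of their own, and leaving out the band does not free the counts of the row trend. With only the groups compared, VEGF Trap vs hFc gave 2321 genes, 47.0% of them rises. Direction reversed for the venous list with fry in VEGF-A vs VEGF Trap and Dll4-Fc vs VEGF-A, where the medians of all measured members were 0.0508 and 0.0113. Fry left out the venous genes Slc38a5 and Aplnr, which had no hFc value, so it tested a smaller set. It reversed for C3 in VEGF Trap vs hFc at −0.0106 with the band of rows left out. Leaving rows out can change the probe that stands for a gene. Within slide 4, VEGF-A vs VEGF Trap reversed for the ganglion cell list at 0.0333 and the pigment epithelium list at 0.0228. The ganglion cell list in VEGF-A vs hFc reversed in the direction of its test with the VEGF-A arrays of slide 4 only, at a median of −0.0278. Averaging hFc 1 and hFc 2 gave 1206 genes for VEGF Trap vs hFc, 2210 for VEGF-A vs hFc and 1000 for Dll4-Fc vs hFc. Slide as a random block gave 2769, 1190 and 1742 genes for VEGF-A, Dll4-Fc and VEGF Trap against hFc, at a slide correlation of 0.00269. That block cannot remove a slide difference from them, since hFc filled a slide of its own. Except for the split controls, the cause of the moves in this section was not tested. Arrays limit what can be seen by signal over background, since the Cy3 signal of 84.9 to 91.0% of spots was well above it.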

Other observations

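All tests in this part were chosen after the results were seen. Vxn rose by a log2 of 2.59 (standard error 0.28, 4 arrays in each group, adjusted p = 1.43e-05) after Dll4-Fc and was lower by −1.21 after VEGF-A. Igfbpl1 rose by 1.77 (0.09, adjusted p = 7.25e-09) after Dll4-Fc and was lower by −0.43 after VEGF-A. With outlier spots kept, Neurog2 rose by 3.28 after Dll4-Fc and Dll3 by 1.39 (adjusted p = 4.07e-06).

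B2m, a subunit of antigen-presenting molecules, rose by 2.24 after Dll4-Fc (standard error 0.19, adjusted p = 1.01e-06), Cd74 by 2.93 with 2 hFc arrays measured, and H2-Aa by 2.15. After VEGF-A, B2m rose by 0.69 (adjusted p = 0.0163), and its difference between Dll4-Fc and VEGF-A was 1.56 (adjusted p = 6.15e-06).

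Some vessel genes had hFc values only with outlier spots kept, since the hFc slide lost their spots. With them kept, Slc38a5 fell by 3.41 after VEGF-A and by 0.84 after VEGF Trap. Robo4 rose by 1.58 after VEGF-A and fell by 0.34 after VEGF Trap. Aplnr fell by 1.52 after VEGF-A and by 0.70 after VEGF Trap. The angiotensin precursor Agt, made by retinal glia, fell by 1.24 after Dll4-Fc (standard error 0.09, adjusted p = 3.5e-07) and gave −0.07 after VEGF-A.

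The VEGF-A arrays differed by slide. Between the 2 VEGF-A arrays of slide 3 and the 3 of slide 4, 1200 of 23360 genes differed, 431 higher and 769 lower on slide 3. Dll4-Fc vs hFc, where each group filled a slide of its own, gave 1202 of 22820. The VEGF Trap arrays lay on the same slides, with a single array on slide 4. Their pairs correlated at 0.664 on the same slide and at 0.717 and 0.639 on different slides. The 1200 genes thus cannot be taken as what a slide alone changes. The mean of the ganglion cell genes was −0.818 and −0.720 on the VEGF-A arrays of slide 3 and 0.0223, 0.0388 and 0.163 on those of slide 4, and 9 of 12 of these genes were lower on slide 3 (median log2 −0.76, list test adjusted p = 9.03e-16). The VEGF Trap arrays of the same slide had 0.146 and 0.0697. Basement membrane genes were higher on slide 3 among the VEGF-A arrays, with 0 members called (median log2 0.25, list test adjusted p = 0.0337).

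Lens gene means varied within every group, from −2.68 to 1.21 for hFc, −2.97 to 0.49 for Dll4-Fc, −3.00 to 0.05 for VEGF-A and −2.17 to 1.76 for VEGF Trap.

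Calls against hFc leaned up among probes in the band of rows where the hFc slide held most spots marked as outliers. For VEGF Trap vs hFc, 368 rose and 164 fell there, against 239 and 1014 in other rows. For VEGF-A vs hFc it was 691 and 209, against 906 and 981, and for Dll4-Fc vs hFc 376 and 91, against 384 and 351. In the band the median log2 change of all genes was 0.056 for VEGF Trap, 0.033 for VEGF-A and 0.053 for Dll4-Fc. In other rows it was −0.071, −0.060 and −0.054, so neither part of the array was free of a shift. With the row trend removed, VEGF Trap vs hFc gave 1252 genes, 976 of them shared with the 1785.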
